A study of Gallus gallus with 39 samples.

How the data were processed

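Tracheal RNA of White Leghorn chickens was sequenced on days 1, 3, 5 and 7 after infection with Mycoplasma gallisepticum Rlow or after Hayflick's medium alone. Per the labels, RNA was taken with TRIzol from the cells and content of the tracheal lumen, cleaned on Zymo columns, selected for polyadenylated transcripts and made into stranded libraries. There were 5 infected birds per day, 4 controls on day 1 and 5 controls on days 3, 5 and 7. No bird was sampled on more than 1 day and no control group serves more than 1 day, so that no paired comparison was made.

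The authors deposited 1 Cuffdiff gene table per day, each listing 17934 genes, 13916 of them with a gene symbol. Per the submitters' processing notes, reads were aligned with TopHat2 2.0.1, TopHat and Bowtie2 and tested with Cuffdiff. In the authors' deposited tables each group has 1 pooled value per gene in FPKM (fragments per kilobase of transcript, scaled to the fragments mapped), computed within that day's run. The score in the authors' deposited tables is Cuffdiff's test statistic, as Cuffdiff wrote it. The authors' deposited fold change is the log2 of infected over control FPKM with no pseudocount. The authors' deposited p values carry a q value that equals the Benjamini-Hochberg adjustment over the tested genes of that day, which was checked on each table. The smallest p in each table is 5e-05. Genes without a test numbered 7665 on day 1 and 7433 on day 3, and 7, 6, 6 and 6 genes on days 1, 3, 5 and 7 were left untested for too much data. Values per bird were not used here, since the tables give none. The depth per bird is therefore unknown, no counting interval or detection limit is given for any FPKM, and a high FPKM is the sole sign of a well covered gene. The genome build is not given in the sources used here. Loci in the tables are bundles that can span several genes (16093 distinct loci), so positions are not printed.

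A gene counts as changed on a day where the authors' q was under 0.05 and the test status was OK. Genes changed on all 4 days passed in 1 direction on each, and the expected count is that of independent lists of the same sizes. For the difference between days, the log2 fold changes of 2 days were subtracted and divided by the root of the summed squared standard errors, 2-sided, with Benjamini-Hochberg q over 60878 tests of genes and the 6 pairs of days. The plan was to take each standard error as fold change over test statistic if that statistic behaved as a z score. It did not: the z of the authors' p was 2.12, 2.24, 2.26 and 2.26 times the statistic on days 1, 3, 5 and 7. Standard errors were taken from p instead. Where p was above 0.9, or at the smallest p, the statistic times that factor was used. The procedure was tested on simulated data: of 100 simulated differences of 1 on the log2 scale 39 were called, of 100 differences of 2 84 were called, and of 9926 genes in a pair of days without any difference 3 were called. The simulated fold changes had the normal errors that the test assumes. They therefore do not show whether standard errors taken from p are right for the real data.

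The 33 gene lists were chemokines, pro-inflammatory cytokines, cytokine inhibitors and regulatory T cell genes, toll-like and other pattern receptors, NF-kappaB pathway, interferon-stimulated genes, antigen presentation, T and NK cell, B and plasma cell, macrophage and monocyte, heterophil, antimicrobial and acute phase, complement, cilium and axoneme, multiciliated cell transcription factors, mucus and secretory cell, basal cell and keratin, epithelial junction, ion transport, cell cycle, matrix remodelling, cholesterol synthesis, oxidative phosphorylation, glycolysis, circadian clock, immediate early and heat shock, ribosomal protein, cartilage, skeletal muscle, fibroblast and smooth muscle, endothelial, erythrocyte, and thymocyte and thyroid genes. All were written before the data were examined. Of the symbols in the tables, 11183 match the names of a chicken reference table and 12353 match its names or older ones, and 45 older names were used for list members. For each list and day, Fisher's exact test, 2-sided, compared the share of measured members that rose, and the share that fell, with all other tested genes. The 264 tests were adjusted together by Benjamini-Hochberg, and 72 passed. Among them, the share that rose was larger than in other genes in 54 and smaller in 5, and the share that fell was larger in 12 and smaller in 1. Counts adjusted over the list alone apply the same adjustment to the members' p values. Genes within a list are not independent, so these p values describe the lists rather than birds.

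Genes named were chosen by a rule written before the data were examined: per day the 10 steepest rises and falls with a symbol, q under 0.05 and an FPKM of at least 5 in the higher group; up to 4 passing members per list by size of change, with an FPKM of at least 1; the 8 steepest rises and falls shared by all 4 days; and the genes with the largest or clearest differences between days. Other members are named where 5 or fewer of a list passed, and SLC12A2 as the remaining gene of the 9 that fell on all 4 days; these were chosen after their values were seen. Some members of these lists are not reported here.

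Alternatives tried were q under 0.01 and 0.10, a minimum 2-fold change, a minimum FPKM of 1, adjustment over the 4 days together or by Bonferroni, infinite folds left out, fold changes centred on the day's median, a pseudocount of 1, the mean in place of the median, and standard errors 1.5 times as large. Added after the data were seen were other standard errors at the smallest p, the statistic read as a z score, side lists left out, list members by file symbols alone, and lists at other thresholds. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used, with seed 1 for the 10000 random lists and 1000 bootstrap resamples.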

Results

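Gene expression was measured by RNA sequencing in tracheas of White Leghorn chickens infected with the virulent strain Rlow of Mycoplasma gallisepticum, a bacterium without a cell wall that lives on the airway surface of poultry. Control birds received Hayflick's medium, the broth in which mycoplasmas are grown. RNA came from the cells and content of the tracheal lumen on days 1, 3, 5 and 7. Each day had 5 infected birds, with 4 control birds on day 1 and 5 on each later day, so that 39 birds entered the study and each bird belongs to 1 day. The authors' deposited tables list 17934 genes per day with 1 pooled FPKM for each group, so no value below has a spread between birds of its own, and the sequencing depth per bird is unknown. A test result was listed for 10269 genes on day 1, 10501 on day 3, 10319 on day 5 and 10502 on day 7. Log2 fold changes are infected over control, and a gene is said to have risen or fallen where the authors' q was under 0.05. The steepest changes are those of genes that passed, have a symbol and reach an FPKM of 5 in the higher group. In gene lists with 5 or fewer passing members, members were chosen to be named after their values were seen. The median standard error, taken from the authors' p, was 0.24, 0.19, 0.33 and 0.31 on days 1, 3, 5 and 7. Fewer calls in a list on days 5 and 7 thus need not mean smaller changes. List counts and medians cover only members with a test, and these differ between days. Of 27 T and NK cell genes in the tables, 9, 21, 17 and 20 had a test on days 1, 3, 5 and 7. On day 1, 10 of 20 pro-inflammatory cytokine, 14 of 28 antimicrobial and 10 of 23 mucus genes had one. Whether low genes were tested mainly where infected birds were high was not examined.

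The comparison on day 1 asks how the trachea differed from that of control birds 1 day after infection. In the authors' deposited table for day 1, 1042 genes rose and 873 fell, or 18.6% of those tested. The steepest rise was that of OGCHI, which encodes the acute phase protein alpha-1-acid glycoprotein, from 2.46 to 162 FPKM in the authors' deposited table (log2 fold change 6.04, q = 0.0124). MMP7 (ENSGALG00000017184), a secreted protease of injured epithelium, rose 48.4-fold to 2877 FPKM, and OLFM4 (ENSGALG00000016943), a secreted glycoprotein of mucosal epithelium, rose 41.1-fold to 2229 FPKM in the authors' deposited table (both q = 0.000744, the smallest q of that day). The authors' deposited table also had rises of AVD, the biotin-binding protein avidin (log2 fold change 5.28), and of CA4, a carbonic anhydrase of the cell surface (5.40). NOX1, an oxidase that makes superoxide, and NOXO1, the protein that organises it, rose by log2 fold changes of 4.88 and 5.11 in the authors' deposited table. Among the 10 steepest rises were also TAC1, the precursor of substance P, at 5.46 and CALCA, the calcitonin precursor, at 5.03 in the authors' deposited table.

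The steepest fall of day 1 was that of TNXB, which encodes the matrix protein tenascin X, with a log2 fold change of −5.09 (q = 0.0124) followed by IGFBP5, a binding protein of insulin-like growth factors, at −4.44 (q = 0.00191) in the authors' deposited table. S100B, a calcium-binding protein, had a log2 fold change of −2.31, and APITD1, named for a kinetochore protein, fell from 527 to 105 FPKM in the authors' deposited table. The other falls among the steepest 10 in the authors' deposited table were XG (−2.87), ACTC1, the cardiac muscle actin (−2.51), SLC16A12, a transporter of small organic molecules (−2.44), CHANK1 (−2.35), CHANK2 (−2.27) and PCTP, a phosphatidylcholine carrier (−2.20).

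**Figure D1:**
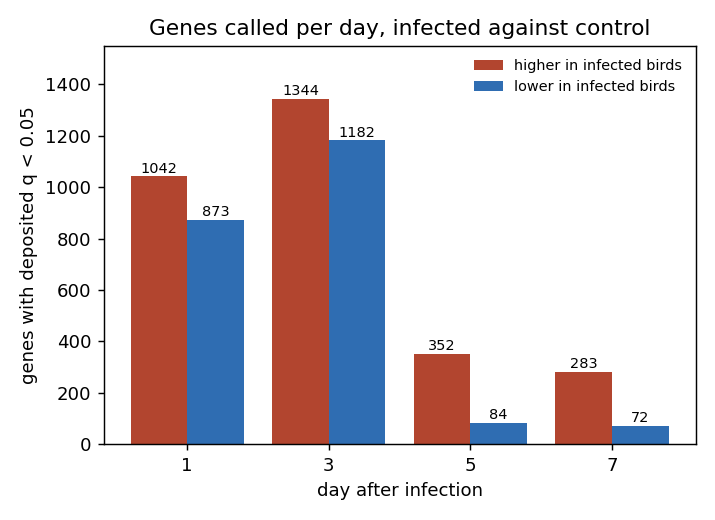
Number of genes per day (horizontal axis, day after infection) with a q under 0.05 in the authors' deposited tables (vertical axis, genes), in red those higher and in blue those lower in infected birds. Days 1 and 3 had 1915 and 2526 such genes and days 5 and 7 had 436 and 355.

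Several lists of inflammatory mediators rose on day 1. Of the chemokines, 7 of 12 (7 adjusted over the list alone) rose (Fisher's exact test, adjusted p = 0.000368), with log2 fold changes of 4.20 for CCL4 (ENSGALG00000000951), a chemokine for monocytes and T cells, and 3.24 for K60, a relative of interleukin 8, in the authors' deposited table. Pro-inflammatory cytokine genes rose in 5 of 10 (7 adjusted over the list alone) cases (Fisher's exact test, adjusted p = 0.00818), with IL-1BETA, IL16, LITAF, TNFSF10 and LIF higher and IL15 alone lower. IL-1BETA, the first interleukin of many inflammatory responses, went from 6.6 to 68.5 FPKM in the authors' deposited table. Of cytokine inhibitors and regulatory T cell genes, 3 of 10 (6 adjusted over the list alone) rose (Fisher's exact test, adjusted p = 0.221), namely SOCS3, which damps cytokine signalling, IL1R2 and IL13RA2, which are decoy receptors. Their log2 fold changes were 4.31, 4.48 and 5.41 in the authors' deposited table. In the NF-kappaB pathway 6 of 17 (7 adjusted over the list alone) rose (Fisher's exact test, adjusted p = 0.02) and 1 fell, ITA, and NFKB2, a subunit of the transcription factor, had a log2 fold change of 1.72 in the authors' deposited table. Of the toll-like and other pattern receptors, 4 of 20 (5 adjusted over the list alone) rose (Fisher's exact test, adjusted p = 0.351): TLR4, the receptor of bacterial lipopolysaccharide, LY96, its partner, MYD88, the adaptor of toll-like receptors, and TLR15, a receptor of birds and reptiles. TLR4 had a log2 fold change of 4.96 and TLR15 of 4.32 in the authors' deposited table. Interferon-stimulated genes did not pass as a list (Fisher's exact test of the 2 of 23 (4 adjusted over the list alone) that rose, adjusted p = 1): USP18 was among those that rose, while MX and IFIT5, both antiviral effectors, fell. The controls of day 1 were high for these genes: 20, 21 and 21 of the 23 genes were higher in controls of day 1 than in those of days 3, 5 and 7 in the authors' deposited tables, a comparison chosen after the values were seen. The median log2 ratio of day 1 to days 3, 5 and 7 was 0.66, 0.61 and 0.60 in controls and −0.14, 0.20 and 0.66 in infected birds of the authors' deposited tables, each normalised by day. Infected birds of day 1 were thus also higher than those of day 7. IFIT5 was at 960.4 FPKM in control and 616 FPKM in infected birds of day 1, and at 266, 208 and 247 FPKM in the controls of days 3, 5 and 7 in the authors' deposited tables.

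Several lists of immune cell and defence genes rose on the same day. Heterophil genes, markers of the granulocyte of birds, rose in 10 of 14 (10 adjusted over the list alone) cases and 1 fell, ALOX5AP (Fisher's exact test of the rise, adjusted p = 1.34e-06). EX-FABP, a lipocalin that binds bacterial iron carriers, went from 586 to 13450 FPKM, and CSF3R, the receptor of granulocyte colony-stimulating factor, had a log2 fold change of 4.30 in the authors' deposited table. Antimicrobial and acute phase genes rose in 10 of 14 (10 adjusted over the list alone) cases and 1 fell, NOS2, the inducible nitric oxide synthase (Fisher's exact test of the rise, adjusted p = 1.34e-06). IRG1, the itaconate-making enzyme of macrophages, had a log2 fold change of 3.83 in the authors' deposited table. Of the macrophage and monocyte genes, 6 of 16 (7 adjusted over the list alone) rose (Fisher's exact test, adjusted p = 0.015). SPI1, a transcription factor of myeloid cells, had a log2 fold change of 2.51 and ITGB2, an integrin of leukocytes, of 1.68 in the authors' deposited table. T and NK cell genes rose in 5 of 9 (6 adjusted over the list alone) cases, CD3E, CD3D, CD8A, IL2RG and TRAC (Fisher's exact test, adjusted p = 0.00463). B and plasma cell genes rose in 2 of 9 (2 adjusted over the list alone) cases, IGJ, the joining chain of antibodies, and XBP1 (Fisher's exact test, adjusted p = 0.538). Antigen presentation genes rose in 8 of 14 (9 adjusted over the list alone) cases (Fisher's exact test, adjusted p = 0.000142), including TAP1, which carries peptides to class I molecules. DMB2, a class II chaperone, had a log2 fold change of 2.26 in the authors' deposited table. Of the complement genes, 3 of 12 (4 adjusted over the list alone) rose, C1R, C1S and CD55 (Fisher's exact test, adjusted p = 0.305).

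Lists of epithelial genes differed in direction on day 1. Cilium and axoneme genes fell in 29 of 58 (35 adjusted over the list alone) cases and none rose, with a median log2 fold change of −0.49 (Fisher's exact test of the fall, adjusted p = 1.40e-14). DNAI1, a chain of the dynein motor of cilia, fell from 145 to 76.7 FPKM in the authors' deposited table. The list of multiciliated cell transcription factors also holds genes of centriole assembly and the cell cycle. None of its 11 measured members passed (0 adjusted over the list alone, Fisher's exact test in both directions, adjusted p = 1), and the list's median was −0.14. Mucus and secretory cell genes rose in 7 of 10 (8 adjusted over the list alone) cases (Fisher's exact test, adjusted p = 7.68e-05), among them AGR2, which helps to fold mucins, from 1233 to 4980 FPKM in the authors' deposited table. MUC13, a membrane mucin, and BPIFB3, a secreted protein of the airway, had log2 fold changes of 2.80 and 2.94 in the authors' deposited table. Ion transport genes rose in 9 of 15 (10 adjusted over the list alone) cases (Fisher's exact test, adjusted p = 3.45e-05) and SLC12A2 alone fell, with a log2 fold change of 2.02 for SCNN1A, a subunit of the epithelial sodium channel, and 2.09 for ATP12A, a proton pump, in the authors' deposited table. Of the epithelial junction genes, 3 of 14 (3 adjusted over the list alone) rose, CDH1, CLDN10 and ELF3 (Fisher's exact test, adjusted p = 0.399), and of the basal cell and keratin genes 1 of 18 (1 adjusted over the list alone), KRT14 (Fisher's exact test, adjusted p = 1).

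Cell cycle genes rose on day 1 in 23 of 36 (26 adjusted over the list alone) cases and none fell, with a median log2 fold change of 0.81 (Fisher's exact test, adjusted p = 3.73e-13). MCM5, a subunit of the replicative helicase, was at 1.22 in the authors' deposited table. Matrix remodelling genes rose in 9 of 16 (11 adjusted over the list alone) cases (Fisher's exact test, adjusted p = 6.37e-05). SERPINE2, a protease inhibitor, went from 95.2 to 1372 FPKM in the authors' deposited table, while MMP2, TIMP3 and PLAT fell. Immediate early and heat shock genes rose in 7 of 18 (9 adjusted over the list alone) cases (Fisher's exact test, adjusted p = 0.00606), including EGR1 (1.94) and HSPA5, a chaperone of the endoplasmic reticulum (1.52, both from the authors' deposited table). Cholesterol synthesis genes rose in 5 of 17 (6 adjusted over the list alone) cases, including HMGCS1, MVD and CYP51A1 (Fisher's exact test, adjusted p = 0.0822). Glycolysis genes rose in 4 of 19 (5 adjusted over the list alone), PFKP, PGAM1, LDHA and SLC16A3 (Fisher's exact test, adjusted p = 0.316). Of the circadian clock genes, BHLHE40 rose and ARNTL and HLF fell (2 of 13, 2 adjusted over the list alone lower, Fisher's exact test, adjusted p = 0.638). COX7C was the only oxidative phosphorylation gene to fall (1 of 44, 0 adjusted over the list alone, Fisher's exact test, adjusted p = 0.43), and no ribosomal protein gene passed, against 8.55% of other genes that fell (0 of 61, 0 adjusted over the list alone, Fisher's exact test, adjusted p = 0.0341).

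Among the markers of blood and deeper tissue, erythrocyte genes fell on day 1 in 6 of 8 (8 adjusted over the list alone) cases, including the haemoglobin genes HBAA (−1.01) and HBG2 (−1.14) of the authors' deposited table (Fisher's exact test, adjusted p = 7.47e-05). Skeletal muscle genes fell in 3 of 18 (3 adjusted over the list alone) cases, TNNT3 and 2 genes named PVALB (Fisher's exact test, adjusted p = 0.463). Fibroblast and smooth muscle genes fell in 2 of 13 (1 adjusted over the list alone), COL1A2 and DMN (Fisher's exact test, adjusted p = 0.638). Cartilage genes fell in 2 of 4 (3 adjusted over the list alone), COL9A3 and MATN3 (Fisher's exact test, adjusted p = 0.127). None of 5 endothelial genes passed (0 adjusted over the list alone, Fisher's exact test, adjusted p = 1), nor did NKX2-1, the only measured thymocyte and thyroid gene (Fisher's exact test, adjusted p = 1). With the authors' q under 0.01 the day 1 count was 1155, and with at least a 2-fold change it was 806, of which 71.0% were higher against 54.4% of all 1915.

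On day 3 the same comparison, in other birds, had the most genes of the 4 days, 1344 that rose and 1182 that fell in the authors' deposited table, or 24.1% of those tested. MMP7 went from 4.82 to 2887 FPKM in the authors' deposited table, a 599.5-fold rise (q = 0.00054, the smallest q of that day). On day 1 it was at 59.5 FPKM in controls and 2877 FPKM in infected birds of the authors' deposited tables. The larger fold of day 3 thus lies in the controls. K60 was at 3.79 and 0.70 FPKM in controls of days 1 and 3, and at 35.8 and 35.6 FPKM in infected birds of the authors' deposited tables. Other steep rises in the authors' deposited table were AVD (log2 fold change 6.35), IL13RA2 (5.82), CCL4 (5.72), K60 (5.67), NOX1 (5.31), OLFM4 (5.34), EX-FABP (5.12), ENPP3, an enzyme that cleaves nucleotides outside the cell (5.32), and DUOXA1, which matures an oxidase that makes hydrogen peroxide (5.51). The steepest falls in the authors' deposited table were those of AHSG, the plasma protein fetuin (−3.91), KCNAB1, a potassium channel subunit (−3.73), SMYD3, a lysine methyltransferase (−2.80), and SLC27A6, a fatty acid transporter (−2.71). The heat shock protein CRYAB (−2.19), the muscle genes MYL3 (7.89 and 1.85 FPKM in control and infected birds) and MB (−2.01), MAL (−1.97), PCBP3 (−1.94) and the endocytic adaptor DAB2 (−1.91) completed the 10 steepest falls of the authors' deposited table.

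Interferon-stimulated genes rose on day 3 in 21 of 23 (22 adjusted over the list alone) cases and none fell, with a median log2 fold change of 0.84 (Fisher's exact test, adjusted p = 4.01e-15). RSAD2, an antiviral enzyme, rose from 14.8 to 111 FPKM, and IFIT5 from 266 to 948 FPKM in the authors' deposited table. Antigen presentation genes rose in 16 of 16 (16 adjusted over the list alone) cases (Fisher's exact test, adjusted p = 3.16e-13). The class II gene BLB1 had a log2 fold change of 1.85 and TAP1 of 2.18 in the authors' deposited table. Chemokine genes rose in 8 of 11 (8 adjusted over the list alone) cases (Fisher's exact test, adjusted p = 7.41e-05). Pro-inflammatory cytokine genes rose in 6 of 9 (7 adjusted over the list alone) cases (Fisher's exact test, adjusted p = 0.00145). Cytokine inhibitors and regulatory T cell genes rose in 7 of 12 (8 adjusted over the list alone) cases (Fisher's exact test, adjusted p = 0.0014). IFNG, a pro-inflammatory cytokine of T and NK cells, had a log2 fold change of 2.93, and CTLA4, an inhibitory receptor of T cells, 2.43 in the authors' deposited table. Pattern receptors rose in 12 of 23 (12 adjusted over the list alone) cases and 1 fell (Fisher's exact test of the rise, adjusted p = 6.37e-05). NF-kappaB pathway genes rose in 8 of 18 (11 adjusted over the list alone) cases (Fisher's exact test, adjusted p = 0.00463), where TRAF3, an adaptor of cytokine receptors, was at 1.28 in the authors' deposited table.

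Markers of lymphocytes and myeloid cells rose with them. T and NK cell genes rose in 14 of 21 (16 adjusted over the list alone) cases (Fisher's exact test, adjusted p = 3.53e-07). CD3D, a chain of the T cell receptor complex, went from 15.4 to 46.2 FPKM in the authors' deposited table. B and plasma cell genes rose in 9 of 16 (9 adjusted over the list alone) cases (Fisher's exact test, adjusted p = 0.000306). Macrophage and monocyte genes rose in 11 of 18 (16 adjusted over the list alone) cases (Fisher's exact test, adjusted p = 2.34e-05). Heterophil genes rose in 9 of 13 (9 adjusted over the list alone) cases (Fisher's exact test, adjusted p = 4.18e-05). CD79B, a chain of the B cell receptor, had a log2 fold change of 1.55, SPI1 2.02 and LYG2 (ENSGALG00000019141), a lysozyme, 4.84 in the authors' deposited table. Antimicrobial and acute phase genes rose in 7 of 14 (7 adjusted over the list alone) cases (Fisher's exact test, adjusted p = 0.00425), and NOS2 and 2 genes named CHIA fell. Complement genes rose in 6 of 13 (8 adjusted over the list alone) cases (Fisher's exact test, adjusted p = 0.0145), and CFI and CD59 fell; CD55, which protects host cells from complement, had a log2 fold change of 2.82 in the authors' deposited table.

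Ribosomal protein genes fell on day 3 in 46 of 61 (55 adjusted over the list alone) cases and none rose, with a median log2 fold change of −0.53 (Fisher's exact test, adjusted p = 3.62e-29). RPS6 went from 2086 to 1026 FPKM and RPL27 from 4150 to 2459 FPKM in the authors' deposited table. Cilium and axoneme genes fell in 15 of 58 (18 adjusted over the list alone) cases and none rose, with a median of −0.29 (Fisher's exact test of the fall, adjusted p = 0.011). DNAL1, a light chain of the dynein motor, had a log2 fold change of −0.98 in the authors' deposited table. In the list of multiciliated cell transcription factors, FOXN4 rose and RFX3 fell (1 of 11, 1 adjusted over the list alone lower, Fisher's exact test, adjusted p = 1). Ion transport genes went both ways, around a median of 0.07, with 7 of 14 (7 adjusted over the list alone) that rose (Fisher's exact test, adjusted p = 0.00425) and 6 of 14 (7 adjusted over the list alone) that fell (Fisher's exact test, adjusted p = 0.0119). Mucus and secretory cell genes rose in 3 of 10 (3 adjusted over the list alone) cases, MUC13, AGR2 and CREB3L1 (Fisher's exact test, adjusted p = 0.326), while ST6GALNAC1 and BPIFB3 fell, the latter from 649 to 221 FPKM in the authors' deposited table. Epithelial junction genes rose in 3 of 14 (3 adjusted over the list alone) cases, CDH1, CLDN10 and ELF3, and 3 of 14 (3 adjusted over the list alone) fell, MARVELD3 among them (Fisher's exact test of the fall, adjusted p = 0.479). KRT14 rose and KRT15 and KRT20 fell among basal cell and keratin genes (2 of 19, 2 adjusted over the list alone lower, Fisher's exact test, adjusted p = 1).

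Cell cycle genes rose on day 3 in 17 of 35 (25 adjusted over the list alone) cases (Fisher's exact test, adjusted p = 4.12e-06). Matrix remodelling genes rose in 9 of 16 (10 adjusted over the list alone) cases (Fisher's exact test, adjusted p = 0.000306), while MMP2, TIMP3 and PLAT fell again. Cholesterol synthesis genes rose in 8 of 17 (9 adjusted over the list alone) cases and STARD4 fell (Fisher's exact test of the rise, adjusted p = 0.0031). HMGCS1, which makes the precursor of mevalonate, had a log2 fold change of 1.07 in the authors' deposited table. Glycolysis genes rose in 7 of 19 (7 adjusted over the list alone) cases and PDK1 fell (Fisher's exact test of the rise, adjusted p = 0.0267). LDHA, a lactate dehydrogenase subunit, had a log2 fold change of 0.81 and SLC2A3, a glucose transporter, of 1.20 in the authors' deposited table. Immediate early and heat shock genes rose in 7 of 18 (7 adjusted over the list alone) cases (Fisher's exact test, adjusted p = 0.02). Oxidative phosphorylation genes fell in 5 of 44 (4 adjusted over the list alone) cases, NDUFA4, NDUFA6, NDUFS4, UQCRQ and COX7C (Fisher's exact test, adjusted p = 1), and none of 44 rose (0 adjusted over the list alone), against 12.9% of other genes (Fisher's exact test, adjusted p = 0.02). Circadian clock genes fell in 4 of 13 (4 adjusted over the list alone) cases, ARNTL, CRY2, TEF and HLF, and BHLHE40 rose (Fisher's exact test of the fall, adjusted p = 0.158).

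Side markers on day 3 were mixed. Erythrocyte genes rose in 3 of 9 (3 adjusted over the list alone) cases, HBAA, HBG2 and SPTB, and CREG1 and TSPO2 fell (Fisher's exact test of the rise, adjusted p = 0.279). Fibroblast and smooth muscle genes fell in 4 of 13 (4 adjusted over the list alone) cases, COL1A1, COL1A2, DCN and LUM (Fisher's exact test, adjusted p = 0.158). Skeletal muscle genes fell in 3 of 17 (3 adjusted over the list alone), MYL2, MYL3 and MB (Fisher's exact test, adjusted p = 0.781). COMP fell among cartilage genes (1 of 3, 1 adjusted over the list alone, Fisher's exact test, adjusted p = 0.638), TEK among endothelial genes (1 of 6, 1 adjusted over the list alone, Fisher's exact test, adjusted p = 0.907) and NKX2-1 as the measured thymocyte and thyroid gene (Fisher's exact test, adjusted p = 0.304). With the authors' q under 0.01 the day 3 count was 1662, and with at least a 2-fold change 820, of which 71.2% were higher against 53.2% of all 2526.

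On day 5 the comparison gave 352 genes that rose and 84 that fell in the authors' deposited table, or 4.23% of those tested. CCL4 had the steepest rise, from 2.73 to 388 FPKM in the authors' deposited table (q = 0.00273, the smallest q of that day). MMP9, a gelatinase stored in granulocytes, followed with a log2 fold change of 6.96, and K60 (6.42), TLR4 (6.12), EX-FABP (5.82), CCLI10 (5.22), IL-1BETA (5.21), TLR15 (4.92), LYG2 (4.90) and SEMA3G, a secreted guidance protein (5.24), made up the 10 steepest rises of the authors' deposited table. Large folds without a pass were listed as well: MMP7 had a log2 fold change of 8.97 (q = 0.739), AVD of 8.31 (q = 0.133) and CSF3R of 6.65 (q = 0.603) in the authors' deposited table. The steepest falls in the authors' deposited table were SMYD3 (−3.94), MBL2, which encodes a collectin that binds microbial sugars (−3.20), ACTC1 (−2.39), VAMP1 (−2.31), the haemoglobin genes HBAD (−2.41), HBAA (−2.27) and HBG2 (−2.25), and the muscle genes MB (−2.25), MYL2 (−2.24) and ACTA1 (−2.24).

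Several immune lists rose on day 5. Antigen presentation genes rose in 7 of 15 (10 adjusted over the list alone) cases (Fisher's exact test, adjusted p = 4.00e-06). Heterophil genes rose in 6 of 13 (8 adjusted over the list alone) cases (Fisher's exact test, adjusted p = 2.43e-05). Chemokine genes rose in 5 of 10 (7 adjusted over the list alone), while MIP-3ALPHA, the chemokine CCL20, fell (Fisher's exact test of the rise, adjusted p = 7.68e-05). BLB1 went from 142 to 906 FPKM in the authors' deposited table. Interferon-stimulated genes rose in 7 of 23 (11 adjusted over the list alone) cases (Fisher's exact test, adjusted p = 7.30e-05). B and plasma cell genes rose in 5 of 17 (11 adjusted over the list alone), CD79B, BTK, IGJ, IRF-4 and CR2 (Fisher's exact test, adjusted p = 0.00119). Macrophage and monocyte genes rose in 5 of 17 (6 adjusted over the list alone), SPI1, ITGB2, LAPTM5, HMOX1 and TLR4 (Fisher's exact test, adjusted p = 0.00119). IGJ went from 42.1 to 249 FPKM in the authors' deposited table. T and NK cell genes did not pass as a list (2 of 17, 2 adjusted over the list alone rose, CD3D and IL2RG, Fisher's exact test, adjusted p = 0.304). Of these 17 genes, 16 had a log2 fold change above 0, and the list's median was 1.22. Pro-inflammatory cytokines rose in 4 of 10 (5 adjusted over the list alone) cases, IL-1BETA, IL16, IFNG and LITAF (Fisher's exact test, adjusted p = 0.00139). Cytokine inhibitors and regulatory T cell genes rose in 3 of 14 (6 adjusted over the list alone), IL1R2, SOCS1 and SOCS3 (Fisher's exact test, adjusted p = 0.0397). NF-kappaB pathway genes rose in 4 of 17 (4 adjusted over the list alone) cases, NFKB2, NFKBIE, IKBKE and MAP3K14 (Fisher's exact test, adjusted p = 0.0103). Pattern receptors rose in 3 of 22 (8 adjusted over the list alone), TLR4, TLR15 and LY96 (Fisher's exact test, adjusted p = 0.125). Antimicrobial and acute phase genes rose in 3 of 14 (8 adjusted over the list alone) cases, DUOX2, DUOXA1 and IRG1, while CP fell (Fisher's exact test of the rise, adjusted p = 0.0397). Complement genes rose in 3 of 13 (4 adjusted over the list alone), C1R, CD55 and SERPING1, while CD59 fell (Fisher's exact test of the rise, adjusted p = 0.0334).

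Matrix remodelling genes rose on day 5 in 6 of 16 (7 adjusted over the list alone) cases and MMP2 fell (Fisher's exact test of the rise, adjusted p = 7.47e-05). Cell cycle genes rose in 7 of 32 (7 adjusted over the list alone) cases (Fisher's exact test, adjusted p = 0.000538). MCM5 went from 4.28 to 18.3 FPKM in the authors' deposited table. Ion transport genes fell in 2 of 15 (4 adjusted over the list alone) cases, ANO1, a chloride channel, and SLC12A2, a chloride importer, while SCNN1A rose (Fisher's exact test of the fall, adjusted p = 0.0253). None of 58 cilium genes passed (0 adjusted over the list alone, median 0.08, Fisher's exact test of the fall, adjusted p = 1), and none of 61 ribosomal protein genes did (0 adjusted over the list alone, median 0.03, Fisher's exact test of the fall, adjusted p = 1). No gene passed among multiciliated cell factors, basal cell and keratin, epithelial junction, cholesterol synthesis and oxidative phosphorylation genes (for each list 0 adjusted over the list alone, Fisher's exact test in both directions, adjusted p = 0.76 for the higher share of oxidative phosphorylation genes and 1 for the rest). ST6GALNAC1 fell among mucus and secretory cell genes (1 of 11, 2 adjusted over the list alone, Fisher's exact test, adjusted p = 0.25). PFKL and SLC16A3 rose among glycolysis genes (2 of 19, 2 adjusted over the list alone, Fisher's exact test, adjusted p = 0.348), NR4A3 among immediate early and heat shock genes (1 of 18, 2 adjusted over the list alone, Fisher's exact test, adjusted p = 0.841) and BHLHE40 among clock genes (1 of 13, 1 adjusted over the list alone, Fisher's exact test, adjusted p = 0.749).

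Markers of muscle, blood and connective tissue fell on day 5. Skeletal muscle genes fell in 8 of 19 (12 adjusted over the list alone) cases, with a median log2 fold change of −1.92 (Fisher's exact test, adjusted p = 3.64e-11). Erythrocyte genes fell in 5 of 9 (6 adjusted over the list alone), HBAA, HBAD, HBG2, RHAG and CREG1 (Fisher's exact test, adjusted p = 1.14e-07). Fibroblast and smooth muscle genes fell in 4 of 12 (7 adjusted over the list alone), COL1A1, DCN, LUM and DMN (Fisher's exact test, adjusted p = 2.34e-05). COMP fell among cartilage genes (1 of 4, 1 adjusted over the list alone, Fisher's exact test, adjusted p = 0.11), none of 4 endothelial genes passed (0 adjusted over the list alone, Fisher's exact test, adjusted p = 1) and neither did NKX2-1 (Fisher's exact test, adjusted p = 1). Without the genes of these muscle, fibroblast, cartilage and erythrocyte lists, 418 of the 436 genes stayed in the count. With the authors' q under 0.01 the count was 230.

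On day 7, 283 genes rose and 72 fell in the authors' deposited table, or 3.38% of those tested. AVD rose 402-fold to 985 FPKM (q = 0.0451) and MMP7 193-fold to 344 FPKM (q = 0.00314, the smallest q of that day) in the authors' deposited table. Genes of B cells were among the steepest rises of the authors' deposited table, with CD72, a B cell receptor co-receptor, at a log2 fold change of 5.87 and IRF-4, a transcription factor of plasma cells, at 4.44. The other steep rises in the authors' deposited table were CSF3R (5.14), MMP9 (4.97), CCLI10 (4.90), CCL4 (4.58), K60 (4.58) and IL2RG, the shared receptor chain of several interleukins (4.46). The steepest falls in the authors' deposited table were LEPR, the leptin receptor (−3.03), MAL (−2.68), COL1A1, a chain of type I collagen (−2.36), EMP1 (−2.18), EFEMP1 (−2.13), LUM, a proteoglycan of connective tissue (−1.97), and MUSTN1 (−1.92). The remaining falls among the 10 steepest in the authors' deposited table were those of the muscle genes MYH4 (−2.05), MYL2 (−2.03) and CKMT2 (8.82 and 2.06 FPKM in control and infected birds).

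Lymphocyte, myeloid and granulocyte markers rose on day 7. T and NK cell genes rose in 8 of 20 (13 adjusted over the list alone) cases (Fisher's exact test, adjusted p = 5.27e-07). B and plasma cell genes rose in 7 of 17 (12 adjusted over the list alone) cases (Fisher's exact test, adjusted p = 2.44e-06). Macrophage and monocyte genes rose in 8 of 19 (13 adjusted over the list alone) cases (Fisher's exact test, adjusted p = 3.53e-07). Heterophil genes rose in 9 of 17 (12 adjusted over the list alone) cases (Fisher's exact test, adjusted p = 4.39e-09). IGJ went from 32.5 to 410.3 FPKM, CD3D from 7.16 to 55.1 FPKM and CYBB, the oxidase subunit of phagocytes, from 0.395 to 7.83 FPKM in the authors' deposited table. Antigen presentation genes rose in 7 of 15 (12 adjusted over the list alone) cases (Fisher's exact test, adjusted p = 1.04e-06). DMA had a log2 fold change of 2.77 in the authors' deposited table. Pattern receptors rose in 7 of 23 (7 adjusted over the list alone) cases (Fisher's exact test, adjusted p = 2.14e-05). Chemokines rose in 4 of 11 (7 adjusted over the list alone), CCL4, CCLI10, IL8 and K60 (Fisher's exact test, adjusted p = 0.000922). Antimicrobial and acute phase genes rose in 5 of 15 (6 adjusted over the list alone), GAL5, DUOX2, DUOXA1, IRG1 and AVD (Fisher's exact test, adjusted p = 0.000242). Lists that did not pass were pro-inflammatory cytokines, with IL-1BETA and IL16 (2 of 8, 4 adjusted over the list alone, Fisher's exact test, adjusted p = 0.0658), cytokine inhibitors, with IL1R2 and SOCS3 (2 of 13, 4 adjusted over the list alone, Fisher's exact test, adjusted p = 0.151), and the NF-kappaB pathway, with NFKB2 and NFKBIE (2 of 18, 4 adjusted over the list alone, Fisher's exact test, adjusted p = 0.245). Their median log2 fold changes were 0.80, 3.29 and 0.19, in that order. CD55 was the complement gene that rose (1 of 13, 1 adjusted over the list alone, Fisher's exact test, adjusted p = 0.638), and none of 23 interferon-stimulated genes rose (0 adjusted over the list alone, Fisher's exact test, adjusted p = 1).

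Matrix remodelling genes rose on day 7 in 6 of 15 (7 adjusted over the list alone) cases and MMP2 fell (Fisher's exact test of the rise, adjusted p = 2.06e-05). MMP13, a collagenase, had a log2 fold change of 3.36 in the authors' deposited table. Ion transport genes fell in 3 of 14 (5 adjusted over the list alone) cases, FOXI1, a transcription factor of ion-transporting airway cells, ANO1 and SLC12A2 (Fisher's exact test, adjusted p = 0.000686). Cell cycle genes rose in 3 of 34 (5 adjusted over the list alone) cases, TOP2A, PLK1 and MCM5 (Fisher's exact test, adjusted p = 0.197). Of these 34 genes, 32 had a log2 fold change above 0, and the list's median was 0.57, against 0.56 on day 5. KRT14 rose among basal cell and keratin genes (1 of 19, 1 adjusted over the list alone, Fisher's exact test, adjusted p = 0.76), BPIFB3 fell among mucus and secretory cell genes (1 of 11, 1 adjusted over the list alone, Fisher's exact test, adjusted p = 0.221) and HLF among clock genes (1 of 12, 1 adjusted over the list alone, Fisher's exact test, adjusted p = 0.235). The basal cell and keratin list had a median of −0.32, with 3 of 19 genes above 0. None of 58 cilium genes passed (0 adjusted over the list alone, median −0.03, Fisher's exact test of the fall, adjusted p = 1), and none of 61 ribosomal protein genes did (0 adjusted over the list alone, median 0.42, Fisher's exact test of the rise, adjusted p = 0.76). No gene passed among multiciliated cell factors, epithelial junction, cholesterol synthesis, oxidative phosphorylation, glycolysis and immediate early and heat shock genes (for each list 0 adjusted over the list alone, Fisher's exact test in both directions, adjusted p = 1 for each). The medians of these lists were −0.04, −0.12, 0.13, 0.33, 0.23 and 0.31, in that order.

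Connective tissue and muscle markers fell on the same day. Fibroblast and smooth muscle genes fell in 7 of 13 (8 adjusted over the list alone) cases, with a median log2 fold change of −1.48 (Fisher's exact test, adjusted p = 3.64e-11). Skeletal muscle genes fell in 4 of 20 (6 adjusted over the list alone), MYL2, PVALB, CKMT2 and MYBPC1 (Fisher's exact test, adjusted p = 7.47e-05). COMP fell among cartilage genes (1 of 5, 1 adjusted over the list alone, Fisher's exact test, adjusted p = 0.114). None of 10 erythrocyte genes passed (0 adjusted over the list alone, median 0.41, Fisher's exact test, adjusted p = 1), none of 5 endothelial genes did (0 adjusted over the list alone, Fisher's exact test, adjusted p = 1) and neither did NKX2-1 (Fisher's exact test, adjusted p = 1). Without the muscle, fibroblast, cartilage and erythrocyte lists the day 7 count was 343 of 355. With the authors' q under 0.01 it was 191, and with q computed over the 4 days together it was 536.

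**Figure D2:**
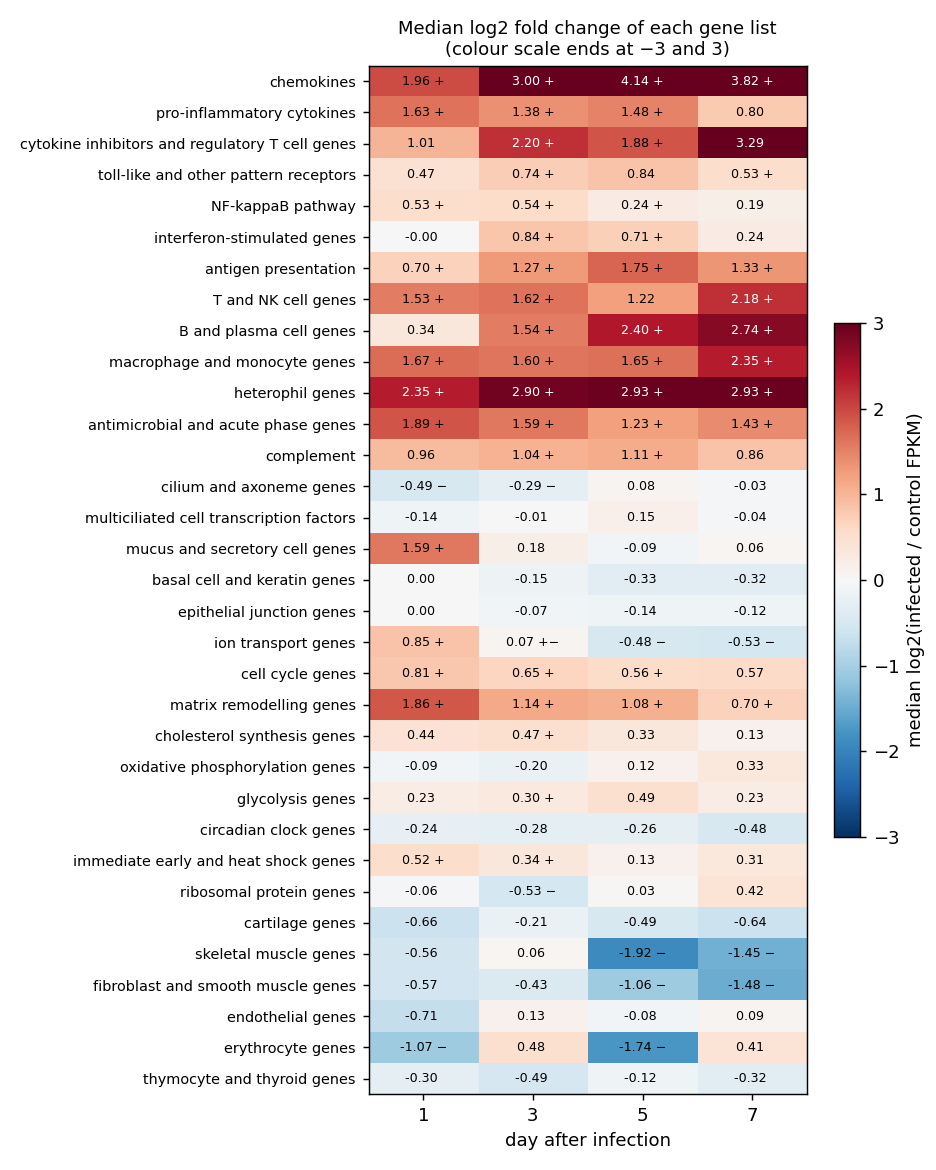
Median log2 fold change (infected over control FPKM, colour and printed value) of the measured members of each gene list (vertical axis) on each day after infection (horizontal axis). A plus sign marks lists with a larger share of genes that rose than among other tested genes and a minus sign those with a larger share that fell (Fisher's exact test, adjusted p under 0.05). Cilium genes have medians of −0.49 and −0.29 on days 1 and 3, and chemokines have medians above 0 on each day.

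Over the week, the question is which differences from control birds were found on each of the 4 days. In the authors' deposited tables, 120 genes rose on all 4 days and 9 fell on all 4, of 9933 genes tested on each day, where independent lists would share 0.0923 and 0.00582. The rises included CCL4, K60 and CCLI10 among chemokines, TLR4 and TLR15 among pattern receptors, NOX1, ENPP3 and MMP9. NOX1 lay between 0.518 and 0.706 FPKM in the control groups and between 11.5 and 21 FPKM in the infected groups of the authors' deposited tables, each normalised by day. SOCS3, IL1R2, LY96, IRG1, NFKB2, DMB2, TAP1, BLB1, IGJ, SPI1, ITGB2, SERPINE2, OLFM4 and CALCA also rose on each day. SERPINE2 had log2 fold changes of 3.85, 3.00, 1.94 and 1.37 on days 1, 3, 5 and 7 in the authors' deposited tables.

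The 9 genes that fell on each day were SLC27A6 (ENSGALG00000000184), PHYHIPL, GCNT1, BCHE, PIWIL1, PAPSS1, MGP, MMP2 and SLC12A2. SLC27A6 had log2 fold changes of −1.85, −2.71, −1.63 and −1.23 on days 1, 3, 5 and 7 in the authors' deposited tables. GCNT1, an enzyme that branches O-glycans, had −1.71, −1.73, −1.23 and −0.89, and PAPSS1, which makes the sulfate donor for glycans, −1.16, −1.35, −1.06 and −1.01 in the authors' deposited tables. BCHE, a cholinesterase, had −1.48, −1.14, −1.58 and −1.34, PIWIL1, a partner of small RNAs, −0.84, −1.41, −1.60 and −1.29, and PHYHIPL −1.62, −1.89, −1.31 and −0.87 in the authors' deposited tables. MGP, an inhibitor of calcification, had −0.82, −0.75, −1.39 and −1.23, and MMP2, a gelatinase of connective tissue, −0.81, −1.03, −1.16 and −1.18 in the authors' deposited tables. SLC12A2 had −0.55, −1.24, −1.35 and −0.96 in the authors' deposited tables. The fibroblast and smooth muscle list had medians of −0.57, −0.43, −1.06 and −1.48 on the same days.

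Pairs of days shared more genes than independent lists would. Days 1 and 3 had 665 rises and 483 falls in common in the authors' deposited tables, against 126 and 99.9 from independent lists, and 42 genes changed in opposite directions. Days 5 and 7 shared 176 rises and 27 falls, against 9.49 and 0.576, with no gene opposite. With the authors' q under 0.01, 61 genes changed alike on all 4 days, and with q under 0.10, 195 did.

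**Figure D3:**
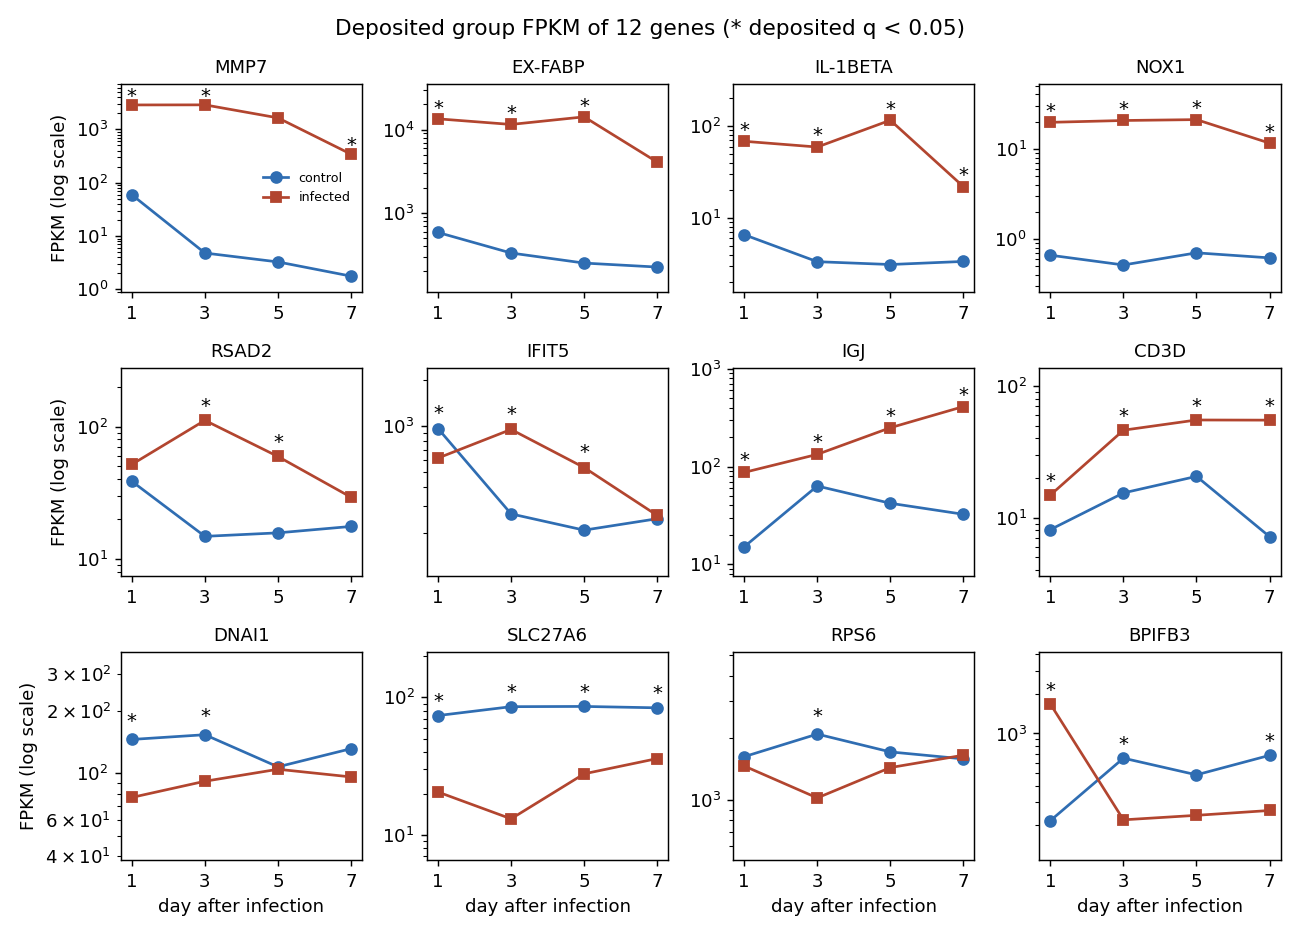
FPKM of the control (blue) and infected (red) group on a log scale (vertical axis) by day after infection (horizontal axis) for 12 genes, with a star where the authors' q was under 0.05; each point is 1 pooled group value, and each day was normalised on its own. RSAD2 has its highest infected value, 111 FPKM, on day 3, and IGJ has its highest, 410.3 FPKM, on day 7.

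The last comparison asks whether the response differed between days, each day with its own birds and controls. Of 10526 genes compared, 470 had a log2 fold change that differed between at least 2 days at q under 0.05. The pairs with day 1 had the most, with 233 genes between days 1 and 3, 202 between days 1 and 5 and 247 between days 1 and 7. There were 63 between days 3 and 5, 95 between days 3 and 7 and 20 between days 5 and 7. Interferon-stimulated genes were among those that differed: the log2 fold change of RSAD2 was 2.49 higher on day 3 than on day 1 (SE 0.285, q = 1.18e-14) and its difference from day 3 to day 7 was −2.18 (SE 0.381, q = 5.78e-06). The difference from day 1 to day 3 was 1.80 for SAMD9L (SE 0.276, q = 6.49e-08) and 0.91 for USP18 (SE 0.235, q = 0.0113). Much of these differences from day 1 to day 3 lies in the controls: RSAD2 went from 38.6 to 14.8 FPKM in controls and from 51.7 to 111 FPKM in infected birds of the authors' deposited tables. From day 3 to day 7, RSAD2 went from 14.8 to 17.6 FPKM in controls and from 111 to 29.3 FPKM in infected birds of the authors' deposited tables, so that difference lies mostly in the infected birds. From day 1 to day 3, SAMD9L went from 12.7 to 4.43 FPKM in controls and from 14.5 to 17.6 FPKM in infected birds, and USP18 from 146 to 63.8 and from 284 to 234 FPKM in the authors' deposited tables. For the 23 interferon-stimulated genes, the median log2 ratio of day 1 to day 3 was 0.66 in controls and −0.14 in infected birds of the authors' deposited tables, each normalised by day, and −0.09 and −0.10 over 9926 genes. Control values moved more than infected values on the log2 scale in 96 of the 233 genes that differed between days 1 and 3, 69 between days 1 and 5 and 54 between days 1 and 7. They did so in 19 genes between days 3 and 5, 18 between days 3 and 7 and 3 between days 5 and 7.

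MUC13 differed by −2.27 from day 1 to day 7 (SE 0.344, q = 4.93e-08), AGR2 by −1.61 (SE 0.366, q = 0.00184), CA4 by −4.59 (SE 0.848, q = 2.53e-05) and HMGCS1 by −1.98 (SE 0.322, q = 5.19e-07). OLFM4 and SERPINE2 differed by −2.34 (SE 0.411, q = 5.92e-06) and −2.48 (SE 0.339, q = 4.12e-10) between the same days. On day 7, the log2 fold change of CD3D lay 2.07 above that of day 1 (SE 0.507, q = 0.00574), IL2RG 2.93 (SE 0.593, q = 0.000198) and CD79B 2.99 (SE 0.647, q = 0.000761). IGJ rose more on day 7 than on day 3, by 2.58 (SE 0.349, q = 2.50e-10). LYG2 differed by 1.81 from day 1 to day 3 (SE 0.277, q = 6.64e-08) and by −2.42 from day 3 to day 7 (SE 0.367, q = 4.41e-08). From day 1 to day 3, LYG2 went from 68.6 to 25.3 FPKM in controls and from 560 to 724 FPKM in infected birds of the authors' deposited tables. From day 3 to day 7 it went from 25.3 to 17.5 and from 724 to 92.9 FPKM in the authors' deposited tables. The first difference thus lies mostly in the controls and the second mostly in the infected birds.

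HBAA, a haemoglobin gene, differed by −2.84 from day 3 to day 5 (SE 0.464, q = 6.60e-07) and 3.44 from day 5 to day 7 (SE 0.736, q = 0.000642). From day 3 to day 5, HBAA went from 461 to 1510 FPKM in controls and from 686 to 314 FPKM in infected birds of the authors' deposited tables. For RPS6, the ribosomal protein gene with the steepest fall on day 3, the differences from day 3 to the other days did not pass, with q = 0.066 for day 1, q = 0.699 for day 5 and q = 0.27 for day 7. RPS23, another ribosomal protein gene, did differ from day 3 to day 7, by 1.32 (SE 0.35, q = 0.0159). For DNAI1 no pair of days passed (lowest q = 0.239, from day 1 to day 5). The standard errors behind these tests were derived from the authors' p values, and with each standard error 1.5 times as large 75 genes differed. With the authors' test statistic read as a z score, a choice made after the data were seen, 18 did. For genes at the authors' smallest p, the standard error was extrapolated from the statistic, so the smallest q values rest on that step. Which of the genes named above stay under these alternatives is not given here.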

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

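Tests of larger spread, the split by day of the test of spread alone, and tests of dilution by other cells, of fewer multiciliated cells and of a scale shift were chosen only after the results were seen. The tests of depth, of response size, of gene length, of short transcripts and of the day 3 controls were set down before the result each measures was seen.

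The log2 fold change differed between pairs of days, by a test of the difference itself, in 233 genes for days 1 and 3, 202 for days 1 and 5, 247 for days 1 and 7, 63 for days 3 and 5, 95 for days 3 and 7 and 20 for days 5 and 7. Of the 163 genes named by rule, 59 differed between at least 2 days. The genes with the largest difference between days and calls in opposite directions, or the smallest p, were LEPR, with −6.46 from day 1 to day 7 (SE 1.13), SMYD3, −6.43 from day 1 to day 5 (SE 0.757), MBL2, −5.73 from day 3 to day 5 (SE 0.558), FGB, a fibrinogen chain, −5.50 from day 1 to day 3 (SE 0.559) and MYH4, a muscle myosin, 4.33 (SE 0.485). From day 1 to day 3, IFIT5 differed by 2.47 (SE 0.255), BPIFB3 by −4.50 (SE 0.287) and INCENP, a protein of dividing chromosomes, by −3.13 (SE 0.291). The controls carry much of some of these: between the same days, control and infected values of LEPR went from 0.304 to 18.4 and from 3.27 to 2.25 FPKM in the authors' deposited tables. Those of SMYD3 went from 1.77 to 25.8 and from 9.94 to 1.69, of MBL2 from 6.08 to 73.6 and from 35.1 to 8, and of IFIT5 from 960.4 to 266 and from 616 to 948 FPKM in the authors' deposited tables. Birds, controls and normalisation differ between days, and no biological explanation of single genes was tested.

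Fewer genes were called on days 5 and 7 than on days 1 and 3. With the day 3 standard errors in place of each day's own, day 5 had 2352 calls against 432 and day 7 had 2172 against 348, ratios of 5.44 and 6.24, but smaller errors add calls whatever the responses, so this leaves larger spread between birds or libraries open. The day 3 fold changes were therefore tested with the standard errors of the later days. Larger spread alone, with responses as on day 3, is argued against as the whole cause on day 7. There the day 3 fold changes gave 649 calls, 1.86 times (95% interval over genes 1.63 to 2.09) those of the day's own fold changes. On day 5 they gave 537, or 1.24 times (1.09 to 1.42), which is within the 1.5 times chosen for the test but does not decide it. The day 3 fold changes carry the smaller errors of day 3. Both counts thus tend to be lower than the same responses measured with the later errors would give. Both are below the 2526 calls of day 3, but how much of the drop larger spread accounts for cannot be told from them. Lower sequencing depth as the whole cause is argued against by genes with an FPKM of at least 100. Their standard errors were 1.90 (95% interval over genes 1.90 to 1.91) and 1.76 (1.76 to 1.77) times those of day 3 on days 5 and 7. The intervals over genes given here carry no spread between birds. For 1861 genes called on day 1, the median log2 fold change was signed by that call. It was 0.602 (0.554 to 0.649) and 0.467 (0.423 to 0.510) times its day 3 value on days 5 and 7. Responses of these genes were thus smaller on both days, but the larger drop set down as the test's bound was not reached on both. Smaller responses as the cause of fewer calls therefore stay open. The day of sampling, its birds and its libraries cannot be told apart here.

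Cilium genes were lower on days 1 and 3. Dilution of epithelial RNA by other cells was tested with epithelial junction genes, which it should lower as much as cilium genes. On day 1 the junction median lay 0.493 above that of cilium genes (95% interval 0.239 to 0.748). That gap argues against dilution alone, with no other change in epithelial genes, on day 1. On day 3 the gap was 0.211 (−0.04 to 0.461), and dilution stays open. The junction list is not a fixed gauge: CDH1, CLDN10 and ELF3 rose on day 1, as did mucus and secretory cell genes. Dilution together with such rises therefore stays open on day 1 too. Gene length or RNA integrity stays open: of 10000 lists matched on expression and locus length 0% had medians as low, but a locus is a genomic bundle and not a transcript, so this test does not measure transcript length, a limit seen only after its result. Fewer multiciliated cells with no change per cell stays open. The median of the multiciliated cell factor list lay 0.350 and 0.279 above that of cilium genes on days 1 and 3. Some members of that list are also expressed in dividing cells, and cell cycle genes rose on both days. The gap therefore cannot decide the question. Lower transcription of cilium genes per cell may be involved and was not tested on its own.

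Ribosomal protein genes were lower on day 3. On day 7 all 61 were higher in infected birds, with a median of 0.42, though none was called. Day 3 control birds with high ribosomal protein RNA are argued against as the whole cause. Their share of summed FPKM was 12.7%, within the range of the other controls (11.2%, 12.9% and 10.8% on days 1, 5 and 7) but above days 1 and 7. The infected share was 8.23% on day 3 against 10.6%, 10.9% and 11.8%, the lowest of all groups. The share is a weak gauge, since it also moves with other genes: on day 5 it was lower in infected birds though the list's median was 0.03. A shift of the whole day 3 scale was not decided: the median of all genes lay 0.526 above that of the list (95% interval 0.461 to 0.590), but normalisation within the day holds that median near 0, and the gap restates the pattern. A loss of short abundant transcripts stays open, since the 0% of matched lists that were as low were again matched on locus and not on transcript length. A lower ribosomal protein share in infected birds of day 3 remains a hypothesis, and a library batch of those birds, which no source used here gives, may produce it too.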

How the results depend on the processing

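Leaving out the side lists, the statistic as a z score, the z of the smallest p and all alternatives of the gene list tests were chosen only after the results were seen. Leaving out each bird, pseudocounts of 0.1 and 5 per bird and other splits of the birds were not run, since the tables hold no values per bird. For the same reason a bird far from its group could not be looked for.

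With the authors' q under 0.01, 1155, 1662, 230 and 191 genes changed on days 1, 3, 5 and 7, against 1915, 2526, 436 and 355, since fewer genes pass a stricter threshold. With at least a 2-fold change the counts of days 1 and 3 were 806 and 820, and after centring 807 and 822, and the share higher moved to 71.0% and 71.2% (71.7% and 71.8% after centring) from 54.4% and 53.2%. With q over the 4 days together the day 7 count was 536. Bonferroni adjustment of the Cuffdiff p gave 0 on each day, because the smallest p of 5e-05, reached by 690, 970, 189 and 163 genes, lies above its threshold. Counts within 1.5 times those reported came from the other alternatives: q under 0.10, an FPKM of at least 1 (which leaves 10264 of 10269 genes on day 1 and so tests little), infinite folds left out, centring alone (which moves values by at most 0.03), and the muscle, fibroblast, cartilage and erythrocyte lists left out (1902, 2513, 418 and 343).

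Genes changed alike on all 4 days numbered 61 at q under 0.01 and 195 at q under 0.10, against 120 higher and 9 lower. Genes that differed between days numbered 294 at q under 0.01, 75 with standard errors 1.5 times as large, 18 with the statistic as a z score and 196 with the smallest p given its own z, against 470, so the count depends on the standard errors. Of 264 list tests, 72 passed, and also 72 with file symbols alone and with an FPKM of at least 1, and 53 at q under 0.01. Of 628 values of named genes by day, 75 lost their call at q under 0.01, and none changed direction with centring. Of 128 list medians, 20 moved by more than their bootstrap SD with a pseudocount of 1 and 28 with the mean. Mean and median differed in sign for interferon-stimulated genes on day 1 and for multiciliated cell factors, skeletal muscle and endothelial genes on day 3, none of which passed a test there. Depth per bird is unknown, so what it limits cannot be given.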

Other observations

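INCENP, chosen after its values were seen, was listed at 220.1 and 859 FPKM in the control and infected groups of day 1 and at 261 and 116 FPKM on day 3 in the authors' deposited tables. MCM5, a cell cycle gene, was listed at 4.51 and 10.5 FPKM on day 1 in the authors' deposited tables. Whether the reads counted for INCENP come from that gene was not tested.

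BPIFB3 was listed at 218 and 1674 FPKM on day 1 and at 649 and 221 FPKM on day 3 in the authors' deposited tables. It belongs to a gene family with neighbouring members, and how reads were divided among them was not tested.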
